A study of Homo sapiens with 18 samples.

How the data were processed

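RNA sequencing was carried out on 18 libraries from 3 human chordoma cell lines, UCH1, MUG-Chor and UM-Chor. Each line was treated with the vehicle DMSO or with KDOBA67, which gives 6 groups of 3 libraries. RNA was taken up in TRIzol and libraries were made with a NEBNext Ultra RNA kit, per the labels' protocols. The deposited table holds whole-number counts per Ensembl gene and library, with no normalization, as its values show. The tool HISAT2 2.1.0 and the human build hg19 are named, per the submitters' processing notes. The counting program, the gene annotation, the strand setting, the dose and the time of treatment are not given in the sources used here. Reads of overlapping or antisense genes therefore could not be told apart, and reads shared by near-identical genes may have been split or dropped by the counting. The labels number the libraries 1 to 3 within each group. Nothing in them says that the libraries came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The labels give no sequencing batch.

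The table holds 20167 genes. A table of gene names matched 19299 of the identifiers to a symbol, and the 868 without a match held 0.599% of the counts and stayed in the fit. No entry named anything other than a gene, and every column belonged to a sample. Total counts ranged from 17709773 to 22499276 per library. No pair of replicates agreed within sampling noise, since the lowest chi-square per degree of freedom between replicates of a group, over genes with at least 20 counts, was 1.36. All 18 libraries were therefore kept as separate samples.

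Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr, which left 14711 genes with 99.973% of the counts, and libraries were scaled by the trimmed mean of M-values (TMM). A model with a mean for each of the 6 groups was fitted to all libraries with the robust quasi-likelihood method, with 12 residual degrees of freedom. The biological coefficient of variation was 3.84%. Contrasts compared KDOBA67 with DMSO in each line, the average of these 3 differences, the difference of the responses for each pair of lines, and the 3 lines in DMSO. The test was the two-sided quasi-likelihood F test, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. Log2 fold changes are KDOBA67 over DMSO, each with its standard error (SE), and CPM values (counts scaled to 1e6 per library) use the TMM-scaled library sizes and are given with the standard deviation (SD) over 3 libraries. A gene counted as changed in all 3 lines when it passed in each line in the same direction. The number of such genes that independent calls would give was computed from the calls of each line, and the lines share no control libraries. They do share the estimate of the spread, and a gene with many counts is more easily called in every line. That number may therefore be too low.

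The test was tried on simulated data for 14284 genes, drawn from the real means and library sizes. Of these, 386 genes were changed in UCH1 and 193 in each of MUG-Chor and UM-Chor. In the real data 63% to 75.2% of the genes were called in a line, so the rates below may not carry over. In UCH1 the test found 59.4% of genes changed 1.2-fold, 81.4% at 1.5-fold, 83.5% at 2-fold and 95.8% at 4-fold, with 20 unchanged genes called. For the same sizes it found 53.1%, 87.8%, 81.6% and 95.7% in MUG-Chor with 2 unchanged genes called, and 53.1%, 87.8%, 93.9% and 93.5% in UM-Chor with 11. For genes changed alike in all lines the average contrast found 75.5%, 87.8%, 85.7% and 97.8%, with 15 unchanged genes called. The call in all 3 lines found 36.7%, 79.6%, 77.6% and 87.0%, with 0 unchanged genes called. The difference of responses between UCH1 and MUG-Chor was found for 29.8%, 64.6%, 75.0% and 88.0%, with 5 unchanged genes called, and that between UCH1 and UM-Chor for 29.8%, 64.6%, 77.1% and 92.0%, with 7. No simulated gene differed between MUG-Chor and UM-Chor, and 0 were called. The camera test described below found a list of 20 genes all raised in UCH1, and it called 0, 1 and 2 of 100 random lists in UCH1, MUG-Chor and UM-Chor. Simulated genes were drawn independently of each other, so these lists cannot show how camera acts on correlated genes. The estimated correlation was 0.87 for the real list of mitochondrially encoded genes.

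The contrasts, the 25 gene lists, the rule for named genes and the alternatives, apart from the exceptions named in the closing section, were fixed before the data were examined. Lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the lists and the 4 treatment contrasts, and over the lists and the 3 differences between lines as a separate family. Camera compares a list with the other genes. The named genes are TBXT, KDM6A and KDM6B. In each line they include the 8 largest rises and falls that passed with an absolute log2 fold change of at least 1, a mean CPM of at least 5 in the higher group and no overlap of replicate values. They also include up to 4 called members of each list with the largest change. For the shared response they are the 8 rises and 8 falls called in all 3 lines whose smallest change was largest, and for each pair of lines the 3 highest and 3 lowest differences of response. Identifiers with no symbol, histone genes and genes of the sex chromosomes that tell the sexes apart were left out of the ranked sets. Genes named outside this rule are said to be so.

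A fold against a group with 0 counts over its 3 libraries was computed against a floor of 3 counts over the group and is given as a lower bound. With 1 to 3 counts the ratio of summed counts is given with an exact 95% interval. Such intervals and floors cover counting error only, since the reads carry no molecular identifiers. A list's median was also computed with such genes at their bound. Alternatives were DESeq2 size factors, total counts in place of TMM, no filter on low counts, a filter of CPM 1 in 3 libraries, a fit that was not robust, limma voom, the DESeq2 1.42.0 Wald test, a fit of only the libraries of the contrast, the replicate number as a block, each library left out in turn, and for lists the fry test and camera with an estimated correlation. Genes withheld for evaluation are not reported here.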

Results

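Gene expression was measured by RNA sequencing in 3 chordoma cell lines, UCH1, MUG-Chor and UM-Chor. Chordoma is a bone tumour of the spine and skull base thought to arise from remnants of the notochord, and the transcription factor TBXT (brachyury) is its characteristic marker. Each line was treated with DMSO or with KDOBA67, an inhibitor of the H3K27 demethylases KDM6A and KDM6B, which remove methyl groups from lysine 27 of histone H3. The study asked how blocking these enzymes acts on TBXT and on chordoma cells. Each of the 6 groups held 3 libraries, with total counts between 17709773 and 22499276. Of the 20167 genes in the table, 14711 were tested. The share of counts on the 13 mitochondrially encoded genes moved with the treatment. It was 5.17% ± 0.427 in UCH1 with DMSO and 0.582% ± 0.108 with KDOBA67 (SD, n = 3). In MUG-Chor it was 3.74% ± 0.0503 and 0.132% ± 0.0014, and in UM-Chor 3.39% ± 0.114 and 0.723% ± 0.0449.

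TBXT fell with KDOBA67 in all 3 lines. In UCH1 its level was 939 ± 5.73 CPM with DMSO and 393 ± 18.1 CPM with KDOBA67 (SD, n = 3), a log2 fold change of -1.25 (SE 0.04, edgeR adjusted p = 1.62e-24). In MUG-Chor it went from 921 ± 8.66 to 206 ± 9.21 CPM, a log2 fold change of -2.16 (SE 0.04, edgeR adjusted p = 2.24e-31). In UM-Chor it went from 1200 ± 16.2 to 603 ± 31.7 CPM, a log2 fold change of -0.99 (SE 0.04, edgeR adjusted p = 7.93e-22). KDM6A, a target of the inhibitor, rose in all 3 lines, with log2 fold changes of 0.39 (SE 0.07) in UCH1, 1.30 (SE 0.06) in MUG-Chor and 0.72 (SE 0.06) in UM-Chor. KDM6B, the other target, rose in UCH1 by a log2 fold change of 0.70 (SE 0.10) from 11.5 ± 0.28 CPM and in UM-Chor by 1.63 (SE 0.08) from 16.2 ± 2.63 CPM. In MUG-Chor the gene had 4 counts over the 3 DMSO libraries, all in replicate 3, and 2 counts over the 3 KDOBA67 libraries. The ratio of DMSO over KDOBA67 was 2.24, with an exact 95% interval of 0.322 to 24.8, which includes no change.

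**Figure D1:**
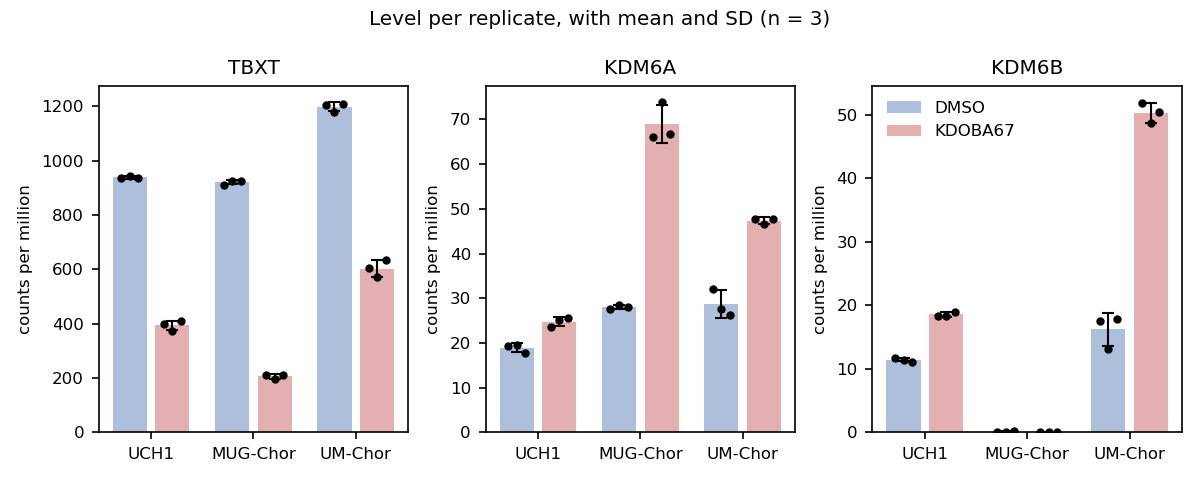
Levels of TBXT, KDM6A and KDM6B in CPM in the 3 lines with DMSO or KDOBA67; points are libraries, bars are means and error bars are SD (n = 3). TBXT fell from 939 to 393 in UCH1, from 921 to 206 in MUG-Chor and from 1200 to 603 in UM-Chor.

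UCH1 cells treated with KDOBA67 had lower expression of notochord genes, cell division genes and mitochondrially encoded genes. Expression of integrated stress response, growth arrest, hypoxia, metallothionein and lysosome genes was higher. The mitochondrial list lost its camera call with an estimated correlation (adjusted p = 0.106). In total 4415 genes rose and 4860 fell, of which 1070 rose and 728 fell at least 2-fold. Among the largest rises were GDF15, a stress-induced cytokine, from 61.0 ± 0.535 to 1164 ± 42.4 CPM (log2 fold change 4.25, SE 0.05, edgeR adjusted p = 2.41e-38). Others were the trypsin inhibitor SPINK1 (5.03, SE 0.11), the innate immune receptor TREM1 (6.19, SE 0.29) and INHBA, a subunit of activin (3.97, SE 0.14). The epidermal genes FLG (5.55, SE 0.18), LCE1B (4.97, SE 0.24) and CSTA (3.96, SE 0.17) were among them too, and LCE1B belongs to a family of close copies whose reads are uncertain. LEP, which encodes leptin, had 3 counts with DMSO and 438 with KDOBA67, a ratio of 135 (exact 95% interval 46 to 659). The largest falls were in the homeobox gene SIX3 (-4.36, SE 0.18), the chemerin receptor CMKLR1 (-3.79, SE 0.13), the myosin light chain MYL10 (-3.75, SE 0.19) and the calcium exchanger SLC24A3 (-3.74, SE 0.12). With them fell the mitochondrial genes MT-CO3, MT-CO1, MT-ATP8 and MT-ND3 (-4.21 to -3.88).

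Of 18 tested genes of notochord and chordoma identity in UCH1, 15 fell, 1 rose and 2 did not pass (median log2 fold change -1.27, camera adjusted p = 1.11e-07). Falls included SHH, a signal secreted by the notochord (-2.63, SE 0.10), the pioneer factor FOXA1 (-2.34, SE 0.06) and SOX9, a regulator of cartilage and notochord (-1.72, SE 0.05). Cartilage and other matrix genes followed with 14 of 26 lower and 3 higher (median -0.47, camera adjusted p = 0.00512, adjusted p = 0.139 with an estimated correlation). The falls included COL9A1 (-2.33, SE 0.13) and the link protein HAPLN1 (-2.24, SE 0.05), while the collagen cross-linking enzyme LOX rose (2.48, SE 0.07). All 28 genes of G2 and mitosis fell (median -1.12, camera adjusted p = 3.71e-17), among them KIF20A (-2.37, SE 0.06) and the mitotic kinase PLK1 (-2.15, SE 0.07). Of 29 genes of S phase and DNA replication 22 fell and 2 rose (median -0.41, camera adjusted p = 2.89e-06), with E2F2 at -1.14 (SE 0.12) and MCM5 at -0.84 (SE 0.06). All 13 mitochondrially encoded genes fell (median -3.46, camera adjusted p = 7.17e-12, adjusted p = 0.106 with an estimated correlation), and their reads may be shared with nuclear copies.

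Of 28 genes of the integrated stress response, the program of the transcription factor ATF4, 27 rose and 0 fell in UCH1 (median 1.47, camera adjusted p = 5.42e-19). The rises included ATF3 (2.87, SE 0.06), the glutathione-degrading enzyme CHAC1 (2.57, SE 0.07) and asparagine synthetase ASNS (2.23, SE 0.04). All 21 growth arrest and DNA damage genes rose (median 1.32, camera adjusted p = 1.88e-15), a list that also holds death-promoting genes such as BBC3. Among them CDKN1A, an inhibitor of cell cycle kinases, went from 386 ± 6.64 to 2061 ± 9.94 CPM (2.42, SE 0.04). In the BCL2 family, which controls apoptosis, 10 of 15 rose and 2 fell (median 0.33, camera adjusted p = 0.00269), and the rises were led by the death-promoting members HRK (2.85, SE 0.43), BBC3 (2.69, SE 0.07) and PMAIP1 (2.44, SE 0.06). Hypoxia targets rose in 24 of 25 cases (median 1.03, camera adjusted p = 1.88e-12), with NDRG1 at 2.72 (SE 0.04) and EGLN3, an oxygen-sensing hydroxylase, at 2.53 (SE 0.05). Of 8 metallothionein and zinc export genes 5 rose (median 2.16, or 1.68 with genes near 0 counts at their bound, camera adjusted p = 0.000129). They included MT1X (3.61, SE 0.09), MT2A (2.44, SE 0.05) and the zinc exporter SLC30A1 (1.87, SE 0.05). MT1X and MT2A have close copies that make their reads uncertain.

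Lysosome and autophagy genes rose in 23 of 27 cases in UCH1 and fell in 3 (median 0.38, camera adjusted p = 5.51e-08), with the autophagy gene MAP1LC3B at 1.03 (SE 0.04) and ULK1 at 1.13 (SE 0.06). Of 17 NRF2 targets 12 rose and 3 fell (median 0.23, camera adjusted p = 0.00269, adjusted p = 0.0727 with an estimated correlation). They were led by the close copies AKR1C1 (2.71, SE 0.08) and AKR1C2 (2.47, SE 0.10), whose reads are uncertain, and by heme oxygenase HMOX1 (2.66, SE 0.04). NF-kB and cytokine genes rose in 11 of 20 cases and fell in 2 (median 0.57, camera adjusted p = 0.0102, adjusted p = 0.101 with an estimated correlation and 0.0549 with total counts as the scale). CSF2 (2.18, SE 0.40) and TNFAIP3 (1.29, SE 0.09) were among the rises. Heat shock genes fell in 13 of 16 cases and rose in 1 (median -0.20, camera adjusted p = 0.0063, adjusted p = 0.366 with an estimated correlation and 0.0542 with total counts). With total counts their median was -0.05. Scaled by TMM, HSPB1 was at -0.75 (SE 0.07) and HSPA8 at -0.47 (SE 0.04).

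The other lists did not stand apart from the remaining genes in UCH1 by the camera test. The modifiers of H3K27 and H3K4 had 11 of 19 higher and 5 lower (adjusted p = 0.466), with the Polycomb subunit PHF19 lower (-1.47, SE 0.05) and the methyltransferase EZH1 higher (0.83, SE 0.07). Iron handling genes had 5 of 10 higher and 3 lower (adjusted p = 0.164), led by the transferrin receptor TFRC (1.34, SE 0.04). Genes of cholesterol and fatty acid synthesis had 10 of 29 higher and 13 lower (adjusted p = 0.637), with a median of -0.08 and a mean of 0.009, and their median was 0.07 with total counts. ER chaperones had 7 of 18 higher and 8 lower (adjusted p = 0.885), with a median of 0.02 and a mean of -0.015. EGFR-MAPK and immediate early genes had 12 of 23 higher and 8 lower (adjusted p = 0.101), led by FOSB (3.71, SE 0.23). Interferon-stimulated genes had 13 of 22 lower and 3 higher (adjusted p = 0.108), and HOX genes 9 of 29 lower and 3 higher (adjusted p = 0.424), where the median of -0.11 became 0.05 with total counts. Housekeeping genes had 7 of 12 lower and 2 higher (adjusted p = 0.122), with actin ACTB at -0.61 (SE 0.04). Among markers of other cell types, 4 of 9 fibroblast genes were lower and 2 higher (adjusted p = 0.235), 2 of 5 blood and endothelial genes lower and 1 higher (adjusted p = 0.615). Of 7 squamous and gland genes 3 were lower and 1 higher (adjusted p = 0.585), with the epithelial cadherin CDH1 at -3.05 (SE 0.09).

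The list counts in UCH1, adjusted over the list alone, were the same except for 8 higher ER chaperones, 13 higher NRF2 targets, 11 higher cholesterol genes and 24 higher lysosome genes. With total counts as the scale the median of all genes moved to 0.143, and 6361 genes rose and 3078 fell, or 67.4% higher against 47.6% with TMM.

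In MUG-Chor, KDOBA67 treatment went with lower notochord, mitotic, cholesterol and mitochondrially encoded genes and with higher integrated stress response, hypoxia and lysosome genes. The growth arrest and DNA damage genes did not stand apart from other genes by camera. The cholesterol and mitochondrial lists lost their camera calls with an estimated correlation (adjusted p = 0.139 and 0.136). In total 5498 genes rose and 5564 fell, of which 1713 rose and 1228 fell at least 2-fold. The largest rises were in SPINK1, from 0.382 ± 0.211 to 37.3 ± 0.332 CPM (log2 fold change 6.56, SE 0.15, edgeR adjusted p = 7.20e-30). Other large rises were in the zinc transporter SLC30A3 (5.73, SE 0.24), the hair keratin KRT34 (5.63, SE 0.22) and the protease TMPRSS11F (5.42, SE 0.30). The death-promoting BCL2 family member HRK (5.37, SE 0.09), the skin collagen COL17A1 (5.29, SE 0.22) and the sodium channel SCN1A (5.26, SE 0.25) followed. RFPL4A (5.81, SE 0.36) was among them, with reads that are uncertain because of close copies. The 8 largest falls were all mitochondrially encoded: MT-CO3 (-6.37, SE 0.15), MT-CO1, MT-CO2, MT-ND6, MT-ND3, MT-ATP8, MT-ATP6 and MT-ND1 (-4.78, SE 0.13). All 13 mitochondrially encoded genes fell (median -5.16, camera adjusted p = 2.36e-10, adjusted p = 0.136 with an estimated correlation).

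Of 18 notochord and chordoma genes 16 fell in MUG-Chor and 0 rose (median -0.96, camera adjusted p = 2.65e-06), with LMX1A at -2.96 (SE 0.31), SHH at -2.34 (SE 0.09) and FOXA1 at -2.25 (SE 0.06). Cartilage and other matrix genes fell in 20 of 26 cases and rose in 3 (median -0.80, camera adjusted p = 0.000718, adjusted p = 0.0879 with an estimated correlation). HAPLN1 (-1.95, SE 0.06) and the cartilage collagen COL2A1 (-1.51, SE 0.05) fell, with LOX higher (1.78, SE 0.08). G2 and mitosis genes fell in 26 of 28 cases (median -0.95, camera adjusted p = 3.53e-10), with PLK1 at -2.43 (SE 0.06) and CDC20 at -2.16 (SE 0.05). Of 29 S phase genes 19 fell and 8 rose (median -0.26, camera adjusted p = 0.0525). Genes of cholesterol and fatty acid synthesis fell in 23 of 29 cases and rose in 2 (median -0.48, camera adjusted p = 2.75e-05, adjusted p = 0.139 with an estimated correlation). The desaturases FADS2 (-1.73, SE 0.06) and FADS1 (-1.09, SE 0.05) were among the falls. Heat shock genes fell in 10 of 16 cases and rose in 3 (median -0.40, camera adjusted p = 0.026, adjusted p = 0.456 with an estimated correlation), with HSPA8 at -1.46 (SE 0.04).

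Integrated stress response genes rose in 25 of 28 cases in MUG-Chor and fell in 2 (median 1.25, camera adjusted p = 8.29e-11), with ATF3 at 4.11 (SE 0.06), GDF15 at 3.52 (SE 0.08) and the amino acid transporter subunit SLC3A2 at 3.22 (SE 0.04). Hypoxia targets rose in 24 of 25 cases (median 1.07, camera adjusted p = 9.47e-11), including ADM (3.15, SE 0.07) and EGLN3 (3.68, SE 0.33). CA9, a carbonic anhydrase, had 1 count in DMSO and 179 with KDOBA67, a ratio of 160 (exact 95% interval 28.3 to 6330). Lysosome and autophagy genes rose in 22 of 27 cases and fell in 2 (median 0.47, camera adjusted p = 2.75e-05), with MAP1LC3B at 2.28 (SE 0.04) and FLCN at 1.61 (SE 0.04). EGFR-MAPK and immediate early genes rose in 16 of 23 cases and fell in 4 (median 0.41, camera adjusted p = 0.00738, adjusted p = 0.187 with an estimated correlation), including FOSB (3.99, SE 0.15) and the growth factor HBEGF (3.65, SE 0.09). H3K27 and H3K4 modifiers rose in 14 of 19 cases and fell in 4 (median 0.33, camera adjusted p = 0.0458, adjusted p = 0.136 with an estimated correlation and 0.0518 with total counts). JARID2, a Polycomb cofactor, rose among them (1.02, SE 0.08), and PHF19 fell (-1.34, SE 0.05).

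The growth arrest and DNA damage genes in MUG-Chor were split, with 9 of 21 higher, 5 lower and 7 not called (median 0.07, camera adjusted p = 0.101). The fry test, which sets a list against no change, gave a rise (fry adjusted p = 5.52e-12). Fry also called the housekeeping genes in this line (fry adjusted p = 4.56e-06), where 75.2% of all genes were called. Its call thus does not set the growth arrest and DNA damage genes apart. Among the latter GADD45A (3.37, SE 0.05), CDKN1A (2.46, SE 0.04) and AEN (1.95, SE 0.04) rose. The BCL2 family had 6 of 15 higher and 5 lower (adjusted p = 0.444), with HRK and PMAIP1 (2.92, SE 0.06) among the rises, and its median of 0.04 became -0.009 without the mitochondrially encoded genes. NF-kB and cytokine genes had 12 of 20 higher and 4 lower (adjusted p = 0.0975), and metallothioneins 6 of 8 higher and 2 lower (median 0.85, adjusted p = 0.0804), with MT1X at 2.47 (SE 0.09). The metallothioneins did pass with no filter (camera adjusted p = 0.0133) and when any 1 of 16 of the 18 libraries was left out (0.0171 to 0.0402). Those fits without 1 library were filtered anew and kept 14887 to 14923 genes against 14711. The filter and the missing library cannot be told apart there, so these values do not strengthen the call. Other camera settings gave up to 0.232. NRF2 targets had 7 of 17 higher and 9 lower (adjusted p = 0.308), with HMOX1 higher (1.83, SE 0.05) and the reductase AKR1B10 lower (-2.39, SE 0.04). Iron handling genes had 4 of 10 higher and 5 lower (adjusted p = 0.705), and ER chaperones 6 of 18 higher and 10 lower (adjusted p = 0.289). Interferon-stimulated genes had 5 of 22 higher and 12 lower (adjusted p = 0.235), and HOX genes 3 of 29 higher and 15 lower (adjusted p = 0.101). Of 12 housekeeping genes 3 were higher and 4 lower (adjusted p = 0.418), with ACTB at -1.51 (SE 0.05), and the sign of their median of -0.01 turned with total counts (0.04). Fibroblast markers had 1 of 9 higher and 7 lower (adjusted p = 0.111), and blood and endothelial markers 2 of 5 higher and 1 lower (adjusted p = 0.526). Squamous and gland markers had 2 of 7 higher and 2 lower (adjusted p = 0.736), with CDH1 at -4.75 (SE 0.19). All list counts in MUG-Chor, adjusted over the list alone, were the same. The call of the H3K27 and H3K4 modifiers was lost in several fits that left out 1 library and were filtered anew. Their camera adjusted p was up to 0.0563, without DMSO replicate 2 of this line.

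In UM-Chor, KDOBA67 treatment went with a fall of mitotic, notochord, cholesterol and mitochondrially encoded genes. It also went with a rise of integrated stress response, growth arrest, metallothionein, NF-kB and lysosome genes. With an estimated correlation the camera calls of the cholesterol, mitochondrial and metallothionein lists were lost (adjusted p = 0.0879, 0.195 and 0.0607). In total 4871 genes rose and 5394 fell, of which 1538 rose and 962 fell at least 2-fold. SPINK1 rose from 0.221 ± 0.0815 to 50.7 ± 4.04 CPM (log2 fold change 7.81, SE 0.16, edgeR adjusted p = 1.15e-31). MYCT1 went from 3 to 568 counts, a ratio of 192 (exact 95% interval 65.3 to 932), and MYBPC1, a muscle myosin-binding protein, from 2 to 352 counts, a ratio of 178 (49 to 1480). Other large rises were in the epidermal lipoxygenase ALOXE3 (6.52, SE 0.15), the aldehyde oxidase AOX1 (6.32, SE 0.11), the immediate early gene FOSB (6.06, SE 0.16), KRT34 (5.97, SE 0.31) and the immune receptor SLAMF7 (5.97, SE 0.10). The largest falls were in MT-ND6 (-3.78, SE 0.14), GPRIN3 (-3.63, SE 0.09), PLK1 (-3.58, SE 0.09), the collagen COL26A1 (-3.53, SE 0.09), the mitotic regulator CDCA3 (-3.33, SE 0.09), GPM6A (-3.24, SE 0.15), MT-CO3 (-3.21, SE 0.12) and HAPLN1 (-3.19, SE 0.10).

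All 28 G2 and mitosis genes fell in UM-Chor (median -1.59, camera adjusted p = 3.86e-16), with the cyclin CCNB1 at -3.19 (SE 0.05) and KIF20A at -2.87 (SE 0.06). Of 18 notochord and chordoma genes 13 fell and 1 rose (median -0.80, or -0.75 with genes near 0 counts at their bound, camera adjusted p = 0.000175), including FOXA1 (-1.92, SE 0.06), SHH (-1.83, SE 0.13) and SOX5 (-1.57, SE 0.09). S phase genes fell in 20 of 29 cases and rose in 4 (median -0.41, camera adjusted p = 0.000324, adjusted p = 0.0727 with an estimated correlation). Cholesterol and fatty acid synthesis genes fell in 24 of 29 cases and rose in 3 (median -0.69, or -0.68 at the bound, camera adjusted p = 5.62e-07, adjusted p = 0.0879 with an estimated correlation). FADS2 (-2.58, SE 0.13) was among the falls. All 13 mitochondrially encoded genes fell (median -2.18, camera adjusted p = 1.11e-07, adjusted p = 0.195 with an estimated correlation). Cartilage and other matrix genes fell in 14 of 26 cases and rose in 3 (median -0.24, camera adjusted p = 0.0376, adjusted p = 0.25 with an estimated correlation). COL3A1, with 0 counts in DMSO and 29 with KDOBA67, was at least 9.79-fold higher.

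Integrated stress response genes rose in 24 of 28 cases in UM-Chor and fell in 3 (median 1.32, camera adjusted p = 4.12e-11). GDF15 went from 55.7 ± 1.73 to 1677 ± 96.8 CPM (4.91, SE 0.05) and ATF3 from 11.6 ± 1.11 to 264 ± 17.1 CPM (4.51, SE 0.06). Of 21 growth arrest and DNA damage genes 18 rose and 0 fell (median 1.82, camera adjusted p = 7.61e-11), including GADD45A (3.69, SE 0.05) and the death-promoting gene BBC3 (3.27, SE 0.07). In the BCL2 family 10 of 15 rose and 2 fell (median 0.63, camera adjusted p = 0.00513), with HRK at 5.24 (SE 0.19), PMAIP1 at 3.07 (SE 0.07) and the death-blocking member MCL1 at 1.30 (SE 0.04). NF-kB and cytokine genes rose in 12 of 20 cases and fell in 1 (median 0.76, camera adjusted p = 0.000854), with TNFAIP3 at 3.36 (SE 0.07) and BIRC3 at 2.41 (SE 0.05). Metallothioneins and zinc export genes rose in 5 of 8 cases (median 2.29, camera adjusted p = 0.00183, adjusted p = 0.0607 with an estimated correlation), with MT1X at 4.44 (SE 0.10) and SLC30A1 at 2.71 (SE 0.05). Lysosome and autophagy genes rose in 23 of 27 cases and fell in 2 (median 0.48, camera adjusted p = 1.17e-06), led among well-measured genes by the autophagy receptor SQSTM1 (2.44, SE 0.04). NRF2 targets rose in 12 of 17 cases and fell in 3 (median 0.92, camera adjusted p = 0.00269, adjusted p = 0.0727 with an estimated correlation), with HMOX1 at 3.39 (SE 0.05) and OSGIN1 at 3.25 (SE 0.08). Hypoxia targets rose in 20 of 25 cases and fell in 2 (median 0.47, camera adjusted p = 5.83e-05, adjusted p = 0.0814 with an estimated correlation), including EGLN3 (2.56, SE 0.05) and the growth factor VEGFA (1.62, SE 0.05).

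The remaining lists did not pass in UM-Chor. ER chaperones had 5 of 18 higher and 10 lower (adjusted p = 0.0907), with PDIA4 at -1.63 (SE 0.04) and HSP90B1 at -1.44 (SE 0.04). EGFR-MAPK and immediate early genes had 12 of 23 higher and 8 lower (adjusted p = 0.0928), with EGR1 at 4.42 (SE 0.10). H3K27 and H3K4 modifiers had 10 of 19 higher and 5 lower (adjusted p = 0.368), heat shock genes 4 of 16 higher and 9 lower (adjusted p = 0.431), and interferon-stimulated genes 7 of 22 higher and 9 lower (adjusted p = 0.585). Iron handling genes had 5 of 10 higher and 4 lower (median 0.44, or 0.15 at the bound, adjusted p = 0.445), with the ferritin chains FTL (1.32, SE 0.05) and FTH1 (1.26, SE 0.05) among the rises. HOX genes had 2 of 29 higher and 11 lower (median -0.66, or -0.02 at the bound, adjusted p = 0.101), and 9 of them were near 0 counts. Housekeeping genes had 5 of 12 higher and 5 lower (adjusted p = 0.816), with ACTB at -1.22 (SE 0.05). Fibroblast markers had 0 of 9 higher and 4 lower (adjusted p = 0.393), with a median of -0.63, or 0 at the bound, and a mean of 0.02. Blood and endothelial markers had 2 of 5 higher and 1 lower (adjusted p = 0.773). Squamous and gland markers had 1 of 7 higher and 1 lower (adjusted p = 0.885), with a median of 0.002, which was -0.009 without the mitochondrially encoded genes, and a mean of -0.17. The list counts in UM-Chor, adjusted over the list alone, were the same except for 4 lower integrated stress response genes, and 1 higher and 9 lower HOX genes.

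**Figure D2:**
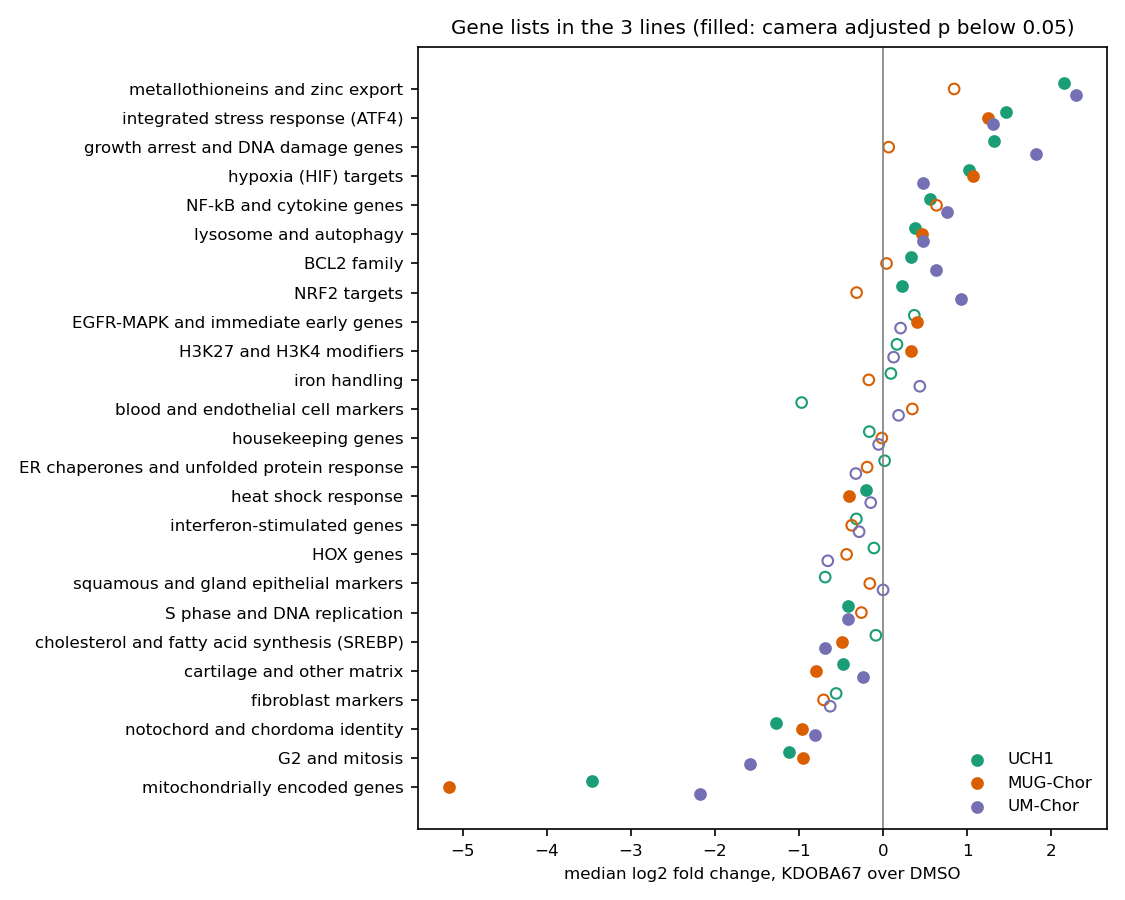
Median log2 fold change of each of the 25 gene lists (KDOBA67 over DMSO) in the 3 lines; filled points passed the camera test with an adjusted p below 0.05. The medians of mitochondrially encoded genes lie between -5.16 and -2.18 and those of integrated stress response genes between 1.25 and 1.47.

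Across the lines, KDOBA67 shifted a shared set of genes. TBXT and other notochord genes, mitotic genes and mitochondrially encoded genes were lower in each line. Integrated stress response, hypoxia and lysosome genes were higher in each line. With an estimated correlation camera did not call the mitochondrial list in any line (adjusted p = 0.106, 0.136 and 0.195) nor hypoxia targets in UM-Chor (adjusted p = 0.0814). A total of 4608 genes changed in the same direction in all 3 lines, 2142 higher and 2466 lower, where independent calls would give 546 and 674. At least 2-fold changes were shared by 337 rises and 189 falls, against 13 and 4 with independent calls. The numbers for independent calls may be too low, since genes with many counts are more easily called in every line. Of the 5988 genes called in all 3 lines, 77.0% moved in the same direction. The rises with the largest smallest change were SPINK1, GDF15, COL17A1, ALOXE3, ATF3, SLAMF7, the cell adhesion gene NECTIN4 and the arginase ARG2, with average log2 fold changes from 6.47 (SE 0.08) for SPINK1 to 3.42 (SE 0.10) for ARG2. The falls were MT-CO3, MT-CO1, MT-CO2, MT-ND6, MT-ND4, MT-ND5, SLC24A3 (-3.22, SE 0.07) and the helicase PIF1 (-2.99, SE 0.07). On average over the lines 5649 genes rose and 5637 fell.

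In the average over the lines, 16 of 18 notochord and chordoma genes fell (median -1.06, camera adjusted p = 1.32e-06), and all 28 G2 and mitosis genes fell (median -1.16, camera adjusted p = 7.25e-14). Of the integrated stress response genes 27 of 28 rose (median 1.42, camera adjusted p = 1.15e-12). The growth arrest and DNA damage genes rose in 18 of 21 cases (median 1.00, camera adjusted p = 1.03e-08), hypoxia targets in 23 of 25 (median 0.85, camera adjusted p = 2.97e-10) and lysosome genes in 24 of 27, with 3 lower (median 0.53, camera adjusted p = 1.21e-06). The lists whose call was lost with an estimated correlation were the mitochondrially encoded genes, all 13 lower (median -3.54, camera adjusted p = 3.39e-09, adjusted p = 0.161 with an estimated correlation), and those below, with both values in this order. Cholesterol genes had 22 of 29 lower and 4 higher (median -0.44, adjusted p = 0.000136, then 0.172) and S phase genes 20 of 29 lower and 6 higher (median -0.41, adjusted p = 0.00106, then 0.0879). Matrix genes had 17 of 26 lower and 5 higher (median -0.51, or -0.52 at the bound, adjusted p = 0.00269, then 0.118). NF-kB genes had 13 of 20 higher and 1 lower (median 0.75, adjusted p = 0.00344, then 0.0727) and metallothioneins 6 of 8 higher (median 1.68, adjusted p = 0.00699, then 0.0882). Heat shock genes had 11 of 16 lower and 3 higher (median -0.23, adjusted p = 0.0328, then 0.465) and the BCL2 family 9 of 15 higher and 3 lower (median 0.29, adjusted p = 0.0371, then 0.0814). HOX genes had 15 of 29 lower and 2 higher (median -0.31, adjusted p = 0.0378, then 0.093). With total counts the heat shock list had an adjusted p of 0.0549, and with the CPM filter the HOX list had 0.058.

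Average lists that did not pass were the H3K27 and H3K4 modifiers (13 of 19 higher, 4 lower, adjusted p = 0.0745) and EGFR-MAPK genes (13 of 23 higher, 8 lower, adjusted p = 0.0873). So were NRF2 targets (12 of 17 higher, 5 lower, adjusted p = 0.0878) and interferon-stimulated genes (14 of 22 lower, 5 higher, adjusted p = 0.166). Iron handling genes (5 of 10 higher, 4 lower, adjusted p = 0.685) had a median of 0.17 that became -0.03 at the bound, and ER chaperones had 10 of 18 lower and 7 higher (adjusted p = 0.289). Of 12 housekeeping genes 6 were lower and 5 higher (adjusted p = 0.427). Fibroblast markers had 4 of 9 lower (median -0.64, or -0.57 at the bound, adjusted p = 0.111) and squamous and gland markers 2 of 7 lower and 2 higher (adjusted p = 0.707). Blood and endothelial markers had 2 of 5 lower and 1 higher (adjusted p = 0.885), where the median of 0.07 and the mean of -0.03 differ in sign. CDH1 fell in all 3 lines, by an average of -3.22 (SE 0.16), as did ACTB (-1.11, SE 0.03). All list counts of the average, adjusted over the list alone, were the same.

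**Figure D3:**
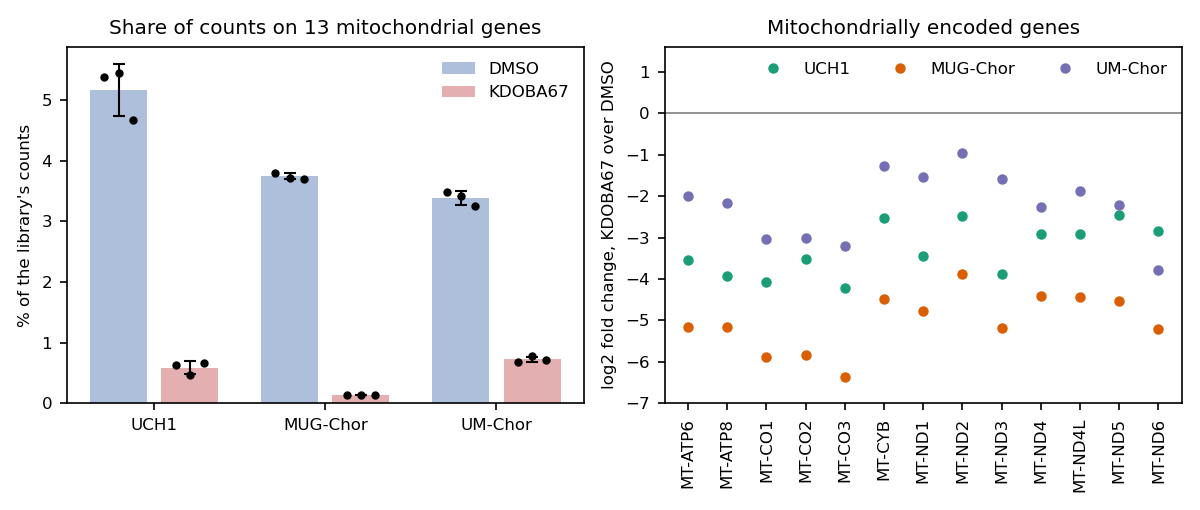
Share of counts on the 13 mitochondrially encoded genes in % per library (left, bars are means, error bars SD, n = 3) and their log2 fold changes, KDOBA67 over DMSO, in the 3 lines (right). The share fell from 5.17% to 0.582% in UCH1, from 3.74% to 0.132% in MUG-Chor and from 3.39% to 0.723% in UM-Chor.

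The responses of the lines also differed from each other, and the test of these differences called 9019 genes between UCH1 and MUG-Chor, 7347 between UCH1 and UM-Chor and 7919 between MUG-Chor and UM-Chor. The fall of TBXT was larger in MUG-Chor than in UCH1 by a log2 difference of 0.91 (UCH1 minus MUG-Chor, SE 0.06, edgeR adjusted p = 1.60e-15) and than in UM-Chor by -1.17 (MUG-Chor minus UM-Chor, edgeR adjusted p = 2.31e-18). The rise of KDM6A was smaller in UCH1 than in MUG-Chor (-0.91) and than in UM-Chor (-0.34), and that of KDM6B smaller in UCH1 than in UM-Chor (-0.94, edgeR adjusted p = 1.56e-07). Across the 14711 genes the fold changes of UCH1 and MUG-Chor had a Pearson correlation of 0.469, those of UCH1 and UM-Chor 0.53 and those of MUG-Chor and UM-Chor 0.56, and genes are not independent replicates. Of the genes called in both lines, 76.8%, 85.7% and 85.5% moved in the same direction in these pairs.

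The growth arrest and DNA damage genes responded less in MUG-Chor than in UCH1 (median difference 1.11, 17 of 21 higher in UCH1 and 2 lower, camera adjusted p = 7.11e-07, adjusted p = 0.0733 with an estimated correlation). They also responded less there than in UM-Chor (MUG-Chor minus UM-Chor -1.42, 18 of 21 lower and 1 higher, camera adjusted p = 1.03e-10). BBC3 had a log2 fold change of 2.69 in UCH1, 3.27 in UM-Chor and 1.32 in MUG-Chor. NRF2 targets showed the same order, with a median difference of 0.83 between UCH1 and MUG-Chor (14 of 17 higher, 1 lower, camera adjusted p = 1.75e-06) and -0.98 between MUG-Chor and UM-Chor (14 lower, 0 higher, camera adjusted p = 1.01e-07). Mitochondrially encoded genes fell further in MUG-Chor than in UCH1 (1.62, all 13 called, camera adjusted p = 2.05e-07, adjusted p = 0.37 with an estimated correlation) and further than in UM-Chor (-2.92, all 13 called, camera adjusted p = 3.28e-11, then 0.188). They fell further in UCH1 than in UM-Chor (-1.05, 11 of 13 lower and 1 higher, camera adjusted p = 5.29e-05, then 0.526).

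Mitotic genes fell further in UM-Chor than in UCH1 (median difference 0.48, 23 of 28 higher and 2 lower, camera adjusted p = 1.01e-07, adjusted p = 0.0733 with an estimated correlation) and than in MUG-Chor (0.86, 24 of 28 higher and 3 lower, camera adjusted p = 7.85e-08, then 0.0733). Camera did not call a change of cholesterol genes in UCH1. Their log2 fold changes were higher there than in MUG-Chor (0.48, 22 of 29 higher and 3 lower, camera adjusted p = 2.72e-05, then 0.236) and than in UM-Chor (0.65, 24 of 29 higher and 1 lower, camera adjusted p = 6.41e-10, then 0.0946). Hypoxia targets rose less in UM-Chor than in UCH1 (0.37, 19 of 25 higher and 2 lower, camera adjusted p = 6.08e-05, then 0.146) and than in MUG-Chor (0.65, 20 of 25 higher and 0 lower, camera adjusted p = 2.05e-07, then 0.0733). Metallothioneins rose less in MUG-Chor than in UCH1 (1.25, or 1.01 at the bound, 6 of 8 higher, camera adjusted p = 0.00807, then 0.146) and than in UM-Chor (-1.33, or -1.05 at the bound, 4 of 8 lower, camera adjusted p = 0.0028, then 0.115). The UCH1 call was lost without UCH1 DMSO replicate 2 or 3 or any of several other libraries. These included KDOBA67 replicates 1 and 3 of UM-Chor, a line outside that comparison (camera adjusted p = 0.0502 and 0.0529). The highest value was 0.0697, without MUG-Chor DMSO replicate 1, and the fit without that library also ended the UM-Chor call (camera adjusted p = 0.05). Such fits were filtered anew and kept more genes, so the filter and the missing library cannot be told apart.

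Smaller differences between UCH1 and MUG-Chor were those of iron handling genes (0.55, 7 of 10 higher and 1 lower, camera adjusted p = 0.0267, adjusted p = 0.115 with an estimated correlation) and of H3K27 and H3K4 modifiers (-0.15, 9 of 19 lower and 1 higher, camera adjusted p = 0.0494, then 0.188). Total counts (0.125), DESeq2 size factors (0.0671) and several fits without 1 library, each filtered anew, ended the call of the modifiers. ER chaperones differed between UCH1 and UM-Chor (0.28, 12 of 18 higher and 2 lower, camera adjusted p = 0.00685, then 0.169). The BCL2 family (-0.16, 7 of 15 lower and 2 higher, camera adjusted p = 0.037, then 0.115) and NF-kB genes (-0.32, 11 of 20 lower and 1 higher, camera adjusted p = 0.0146, then 0.169) differed between MUG-Chor and UM-Chor. The other lists did not pass for any pair. With total counts the median of all genes in UCH1 minus UM-Chor was 0.129, and 65.1% of the called genes were higher against 50.1% with TMM. Adjusted over the list alone, the modifiers had 8 lower in UCH1 minus MUG-Chor, cholesterol genes 25 higher in UCH1 minus UM-Chor, and growth arrest and DNA damage genes 19 lower in MUG-Chor minus UM-Chor. The counts of the other lists named for these differences were the same.

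In DMSO, the 3 lines differed at 14029 of 14711 genes, and 7908 of these differed at least 2-fold between some pair of lines. TBXT was at 939, 921 and 1200 CPM in UCH1, MUG-Chor and UM-Chor. Of the 18 notochord and chordoma genes all 18 differed, 13 of them 2-fold, and of 26 matrix genes all differed, 23 of them 2-fold, with the highest level most often in MUG-Chor (13 genes). Hypoxia targets differed 2-fold for 22 of 25 genes, of which 16 were highest in UM-Chor. Of 21 growth arrest and DNA damage genes 17 differed 2-fold, with 12 highest in UM-Chor, 5 in UCH1 and 0 in MUG-Chor. KDM6B was at 11.5 CPM in UCH1 and 16.2 CPM in UM-Chor, and its 4 counts in MUG-Chor were 0.00615 of the level in UCH1 (exact 95% interval 0.0016 to 0.0152).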

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

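The differences between lines in the next 3 paragraphs were picked out because the responses of 2 cell lines to KDOBA67 differed by a test of the difference itself, and the patterns and the splits after them were not. For the patterns weighed below, the tests of normalization for the mitochondrial genes, of annotation or mapping for KDM6B and of a smaller response for the growth arrest and DNA damage genes were chosen after the result was seen.

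The responses differed at 9019 genes between UCH1 and MUG-Chor, at 7347 between UCH1 and UM-Chor and at 7919 between MUG-Chor and UM-Chor. For TBXT the log2 difference was 0.91 for UCH1 minus MUG-Chor (edgeR adjusted p = 1.60e-15), -0.26 for UCH1 minus UM-Chor (edgeR adjusted p = 0.00028) and -1.17 for MUG-Chor minus UM-Chor (edgeR adjusted p = 2.31e-18). For KDM6A it was -0.91, -0.34 and 0.57 in the same order (edgeR adjusted p = 1.64e-10, 0.00338 and 7.67e-07). For KDM6B it was -0.94 for UCH1 minus UM-Chor (edgeR adjusted p = 1.56e-07).

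The genes with the largest differences between UCH1 and MUG-Chor were MYL10 (-6.3), CA9 (-5.12) and PAEP (-5.09) at the low end and LEP (5.64), LAMC3 (5.13) and ALDH3A1 (4.81) at the high end. Between UCH1 and UM-Chor they were CHRDL1 (-8.82), SH2D2A (-6.28) and CYP24A1 (-6.11) against LEP (6.11), PRDM13 (4.64) and CEACAM6 (4.45). Between MUG-Chor and UM-Chor they were STON2 (-6.47), ABCC9 (-6.08) and NCMAP (-6.06) against DMBX1 (5.63), SCN1A (5.59) and NRCAM (5.11). All but CEACAM6, DMBX1, SCN1A and NRCAM had a group with at most 3 counts in a line compared, so their fitted differences depend on the prior count and are not sizes. Without KDOBA67 replicate 2 of UM-Chor the edgeR adjusted p of CYP24A1 was 0.0567, and with DESeq2 size factors that of LEP between UCH1 and UM-Chor was 0.0501.

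Lists differed by the camera test between UCH1 and MUG-Chor with median log2 differences of -0.15 for H3K27 and H3K4 modifiers, 1.25 for metallothioneins, 0.55 for iron handling, 0.83 for NRF2 targets, 0.48 for cholesterol genes, 1.11 for growth arrest and DNA damage genes and 1.62 for mitochondrially encoded genes. Between UCH1 and UM-Chor the medians were 0.28 for ER chaperones, 0.37 for hypoxia targets, 0.65 for cholesterol genes, 0.48 for mitotic genes and -1.05 for mitochondrially encoded genes. Between MUG-Chor and UM-Chor they were -1.33 for metallothioneins, 0.65 for hypoxia targets, -0.98 for NRF2 targets, 0.86 for mitotic genes, -1.42 for growth arrest and DNA damage genes, -0.16 for the BCL2 family, -0.32 for NF-kB genes and -2.92 for mitochondrially encoded genes. With an estimated correlation only the NRF2 targets of both pairs and the growth arrest and DNA damage genes of MUG-Chor minus UM-Chor kept their call. For the others camera gave adjusted p from 0.0733 to 0.37, from 0.0733 to 0.526 and from 0.0733 to 0.188 in the 3 pairs in this order.

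The 13 mitochondrially encoded genes fell in all lines. The share of raw counts was at least 4.68 times lower with KDOBA67, which argues against normalization. Ribosomal protein genes, also abundant and short, had an average median of -0.022, which argues against their joint loss in library preparation. It cannot exclude a step of the preparation that lost mitochondrial transcripts alone. Nuclear respiratory chain genes had -0.205, far less than the mitochondrial genes, so a joint fall does not account for the size. Genes of the mitochondrial transcription machinery had 0.095 on average, with a lowest member at -0.392. In single lines the lowest member was at -0.437 in UCH1, -0.618 in MUG-Chor and -0.709 in UM-Chor. These values argue against a fall of that list as a whole. The list also holds coactivators and RNA processing genes, so its median cannot exclude a role of single factors. A change in mitochondrial RNA stability, copy number or polymerase activity stays open as a hypothesis, since none of these was measured.

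KDM6B had 4 counts in MUG-Chor with DMSO against 669 in UCH1. Its 11.5 CPM in UCH1 under the same annotation argue against a counting that misses the gene in every line. They cannot show whether reads were missed in MUG-Chor alone. No biological explanation is reported here for the low count.

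The growth arrest and DNA damage genes did not stand apart from other genes in MUG-Chor (camera adjusted p = 0.101). Fry, which sets a list against no change, gave a rise (fry adjusted p = 5.52e-12), but it called the housekeeping genes there too (fry adjusted p = 4.56e-06). High levels before treatment are argued against, since the median log2 CPM of the growth arrest and DNA damage genes was -1.111 relative to the higher of the other lines. A weaker response of all genes is argued against too, since the median absolute log2 fold change was 1.23 times that of the next line. What sets MUG-Chor apart stays open, and no other explanation is reported here.

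Other splits of the libraries were compared with the real one. For genes changed in the same direction in all 3 lines only the real split, 1 of 100, gave as many (4608, highest other 0). The same held for the average (11286, highest other 4674) and the lines in DMSO (14029 and 7601). It held too for UCH1 minus MUG-Chor (9019 and 3522), UCH1 minus UM-Chor (7347 and 750) and MUG-Chor minus UM-Chor (7919 and 2939). Each other split put treated and DMSO libraries, or different lines, in 1 group, which widened the spread and favoured the real split. The 100 for the average and for all 3 lines held none that mixed just 1 line. Such splits cannot test whether a pair of lines responds equally, nor exclude chance between cultures. Within a line only 10 splits exist, too few for a share under 0.05, and the real counts of 9275, 11062 and 10265 stood against highest others of 6, 0 and 0.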

How the results depend on the processing

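The removal of the mitochondrially encoded genes before scaling was added after the data were seen, and all other alternatives were planned. Under every alternative that gave a value, the total number of changed genes in each comparison stayed within 1.5 times its value and TBXT kept its fall in each line. The fit of only the libraries of the contrast gave no value for the average. Total counts moved the number of lower genes in UCH1 from 4860 to 3078. With 1 library left out, counts ranged from 8693 to 9467 in UCH1, 10651 to 11176 in MUG-Chor, 9843 to 10353 in UM-Chor and 11202 to 11298 for the average. They ranged from 4375 to 4606 for all 3 lines, 8640 to 9178, 6886 to 7275 and 7559 to 8002 for the differences of responses in the order used above, and 14016 to 14179 in DMSO. TBXT ranged from -1.28 to -1.22, -2.18 to -2.12 and -1.03 to -0.95. No called result reversed, and the list medians that changed sign with another scaling belong to tests that were not called. Among the list tests, at most 175 per alternative, an estimated correlation between genes ended 44 calls and fry added 86. Total counts ended 5 and added 3, no filter added 10, the CPM filter ended 3 and added 3, DESeq2 size factors ended 1 and added 1, and the scaling without mitochondrial genes did the same. In 18 repeats of these tests, each without 1 library, 21 calls ended, all in 4 of the tests, and 35 were added, in 8 of them. Among the values of named genes, at most 456 per alternative, any alternative with all libraries ended at most 4 calls, and the 18 repeats without 1 library together ended 46, in 14 of the values. Each repeat without a library filtered the genes anew and kept 14887 to 14923 of them, against 14711 in the main fit. The filter and the missing library therefore cannot be told apart in these repeats. The cause of the changes was not tested. Fitted with the replicate number as a block, the counts were 8985, 10882 and 10035 in the lines, 11160 for the average and 4423 for all 3 lines, and 5 list calls and 4 gene calls ended. Libraries of the same number did not pair up: the correlations of 9 pairs ran from -0.091 to 0.135, and 3 of 9 treated libraries correlated best with their own number. In simulation 64.6% of the differences between UCH1 and MUG-Chor were found at 1.5-fold, so genes that were not called may still have changed. Depth and the number of libraries were not varied there, and far fewer genes changed than were called in the data.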

Other observations

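Of 75 nuclear genes of the respiratory chain 61 were lower and 6 higher on average over the lines (median log2 fold change -0.205), and in MUG-Chor 43 were lower and 14 higher. These lists were counted by gene, and no list test was run on them. Cytoplasmic ribosomal protein genes, which supply the protein-making machinery, went both ways, with 25 of 77 lower and 19 higher on average (median -0.022). In UCH1 41 were lower and 2 higher, and in UM-Chor 7 lower and 36 higher. The UCH1 median was -0.142, and total counts as the scale moved the median of all genes there to 0.143. The direction in UCH1 may therefore depend on the scaling, and these lists were not computed with total counts. Genes of mitochondrial transcription and RNA processing had 11 of 21 higher and 6 lower on average. PPARGC1A, a coactivator that drives the making of mitochondria, rose (2.22), as did the mitochondrial RNA helicase SUPV3L1 (1.06). PPARGC1A and SUPV3L1, and LCE1E and LCE1F below, lie outside the rule for named genes and were chosen after their values were seen.

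The test of the next hypothesis was planned before its genes were looked at, and the bound used to score it was added afterwards. The epidermal genes FLG, LCE1B, CSTA, ALOXE3 and COL17A1 were among the largest rises. The hypothesis was that genes of epidermal cornification rise with them. Of 64 such genes other than those named, 27 were tested. In UCH1 16 were higher and 5 lower, in UM-Chor 15 and 5, in MUG-Chor 7 and 5, and on average 12 and 3. A gene near 0 counts with DMSO in every line could pass the count filter only by rising, which favours a rise. Genes that were not tested were not counted, and the list was not tested again without the filter. Camera gave adjusted p = 0.0072 in UCH1, 0.0108 in UM-Chor, 0.891 in MUG-Chor and 0.0108 on average, and 0.0512, 0.0512, 0.906 and 0.0512 with an estimated correlation. The criterion written beforehand, a fitted average median of at least 1, was met with 1.74. After that value was seen, the 10 of the 27 genes that lay near 0 counts were set at their bound, which gave 1.19 and met the criterion too. Over the 17 other genes the median was 0.473, under the 0.5 set beforehand as counting against a shared rise, but that choice of genes leaves out those that rose from 0 counts, such as LCE1E and LCE1F in UM-Chor. The criterion was thus met on average only with the genes near 0 counts, whose selection by the filter favours a rise. It was not met in MUG-Chor, where the median was 0, and the list test did not hold with an estimated correlation. Whether the other genes rise together is therefore not settled by this test.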
